A study of Mus musculus with 2 samples.

How the data were processed

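Single-cell RNA sequencing measured endothelial cells that had been sorted on CD31, a surface protein of endothelial cells, from tumours of adult C57BL/6 mice. Per the labels, the cells were run on the droplet system of 10x Genomics with 3′ v3.1 chemistry. There was 1 library titled control and 1 titled NF2 KO, for knockout of Nf2, the gene of the protein merlin. The tumour type, the number of mice and the exons removed were not given in the sources used here. Cell Ranger 3.0.0, Seurat 3.1.1 and the mm10 build of the mouse genome are named in the submitters' processing notes, without their settings.

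The authors deposited 1 table per library with 19831 genes in each, and the values in it are natural log values. Tested on the values, each one equalled the natural log of 1 plus 10000 times a gene's UMI count divided by the total of its cell, so that whole UMI counts (molecules counted by unique molecular identifiers) could be recovered: 100% of the deposited values came out whole within a tolerance of 0.01 UMI. Counts had been assumed before the data were examined, and the recovered counts took their place. The authors had already filtered the cells before they deposited them, since every cell in the tables held between 501 and 7994 genes and under 10% mitochondrial UMIs. Cell barcodes in each table carried 1 of 2 run numbers, whose meaning the labels do not state. The 2 runs of a library were treated as parts of 1 sample and never as replicates, and the difference between them served as a background for the difference between libraries.

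Cells with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept. Doublets were scored per library by the share of simulated doublets among the neighbours of each cell, after the method of Scrublet. The automatic threshold of that score marked 0.0389% of the control cells and 0% of the knockout cells and so had not worked, and the highest-scoring 5% of each library were removed instead (129 control and 166 knockout cells). The remaining 2443 control and 3146 knockout cells were scaled to 10000 UMIs, log-transformed and clustered on 30 principal components of 2000 variable genes with 15 neighbours and the Leiden method at resolution 0.8, without integration of the libraries. This gave 16 clusters. In 6 of them the median UMI count per cell was below 0.333 of that of their own sample, with no endothelial marker among the 10 leading genes by fold over the other clusters (10 CPM added to both sides). The latter also held for 9 of the other 10 clusters, so within this rule depth set these 6 apart. A further rule left out clusters with at least 2 more leading markers of another cell type than endothelial ones. Of the shallow clusters, 2, 4, 10 and 13 met it as well. Cluster 2 had 4 monocyte or macrophage markers, and the others had 2 neutrophil markers each. Clusters 14 and 15 had no such marker. All 6 shallow clusters were left out: they held 1145 control cells (46.9%, 95% interval 44.9 to 48.9) and 349 knockout cells (11.1%, 10.0 to 12.2). Endothelial markers in them summed to 9779 CPM in the control and 7585 CPM in the knockout library, against 12363 and 9791 CPM in the cells kept. The cells of the other 10 clusters, 1298 in the control and 2797 in the knockout library, are called the retained cells. The sort and the rules above define them, not a cell-type name, because in 3 of their clusters 1 marker of another cell type and no endothelial marker was among the 10 leading genes (Cldn4 in cluster 0, Tagln in cluster 6, Hbb-bs in cluster 11). Cluster 3 had both, Kcnj8 of pericytes and the endothelial marker Cldn5. Those 3 clusters were kept in the main comparison, a choice made after the data were seen. They held 118 control and 1246 knockout retained cells. Cluster 0 (778 cells) and cluster 1 (511 cells) held more of the knockout retained cells than any other cluster, as did cluster 3 (536 cells) and cluster 1 (211 cells) for those of the control. With 1 library per group, a cluster mostly of 1 library may be that library and not a kind of cell.

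UMI counts of the retained cells were summed per library and expressed as CPM, the counts per 1000000 UMIs of that library. With 1 library per group, and runs not known to be replicates, no test between the conditions was made and no p-value was computed. Each CPM has an exact Poisson interval, each ratio of CPM (knockout over control) an exact conditional interval and each share of cells an exact Clopper-Pearson interval, all at 95%. These intervals cover counting error only, not the spread between animals or libraries, and those of a ratio cover the ratio of CPM. A gene was counted as higher or lower in the knockout library where its ratio was at least 1.5 in either direction, its interval excluded 1 and its mean CPM was at least 20. Gene lists were fixed before the data were examined, as were the markers, the size rules, the rule for named genes and the alternatives not described as chosen later. Of the 31 lists, 1 holds only sex-linked check genes and was not scored. The lists hold 516 symbols in all, of which 511 are in the tables, 2 of them under an older symbol (Cyr61 for Ccn1 and Ctgf for Ccn2). For each list the median log2 ratio over members with a mean CPM of at least 5 was placed among 10000 random lists of the same size matched on mean CPM in 20 bins. A list was called higher above the 97.5th percentile and lower below the 2.5th, as a description of these libraries. Lists with fewer than 5 such members received no percentile. Because runs of 1 library also differ, a list was further described as beyond the runs where every pair of runs of different libraries differed, in the called direction, by more than the runs of either library differed from each other. That rule was chosen after the data were seen.

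The genes named by rule were Nf2; the 12 highest and 12 lowest ratios among 2918 genes with a mean CPM of at least 50 whose interval lay wholly beyond 1.5 in either direction; and up to 3 members of each list with a mean CPM of at least 20 whose interval lay wholly beyond 1.25. Ribosomal, mitochondrial, haemoglobin, immunoglobulin and sex-linked genes and unnamed gene models were left out of the second part of the rule. Some genes that the rule names are not reported here. Members named beside them as examples of a list's count were chosen after their values were seen. Retained cells were clustered again at resolution 0.8 without the 2073 genes whose ratio between the libraries was at least 1.25 in either direction, and the ratio of each list was computed within sub-clusters holding at least 50 cells of each library. A sub-cluster was named after a state only from at least 3 of its markers among the 25 leading genes. For the share of cells with G2/M transcripts, each cell was thinned to 2000 UMIs, shallower cells were left out, and cells with at least 2 UMIs of the G2/M list were counted.

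The calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9 and leidenalg 0.10.2, and figures were drawn with matplotlib 3.10.9. The size rule was tested on simulated data for the knockout against the control library with 5796 genes. It called 67 of 67 genes changed 2-fold, 66 of 66 changed 3-fold, 0 of 67 changed 1.25-fold and 0 of 5596 unchanged genes, and the intervals held the true ratio of CPM for 95.3% of the unchanged genes. Of 100 simulated lists without a change, 1 lay outside the random range. The simulated counts came from 1 profile shared by both libraries and held counting error only. These rates therefore do not cover variation between cells, runs or libraries, and the runs of 1 library differed by more, as given below. Gene positions come from GENCODE release M21, an annotation of GRCm38, the assembly that mm10 names. The deposited tables give gene symbols only.

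The alternatives tried were no filter and a stricter filter on cells, doublets kept, other clustering resolutions and cells gated one by one on markers. Scaling was varied by TMM, by median of ratios and by totals without ribosomal, mitochondrial and haemoglobin genes. Further ones were means over cells, thinned cells, dividing cells left out, and other thresholds for genes, lists and dividing cells. Sub-clusters were also given the same weights in both libraries, namely their shares of the pooled cells. Chosen after the data were seen were leaving out each run in turn, keeping the shallow clusters, requiring 5000 UMIs per cell, other resolutions of the sub-clusters, and leaving out clusters 0, 6 and 11 but not cluster 3.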

Results

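The data are the transcriptomes of CD31-sorted tumour endothelial cells labelled as control and as knockout of Nf2, with 1 library per group. Nf2 encodes merlin, a membrane-associated protein that acts upstream of the Hippo pathway, the kinase cascade that restrains the transcriptional coactivators YAP and TAZ. The control library held 2826 cells with 34649992 UMIs in all, and the knockout library 3368 cells with 58907098 UMIs. The median cell of the control library had 2746 UMIs in run 1 (2032 cells) and 19409 UMIs in run 2 (794 cells). In the knockout library it had 14337 UMIs in run 1 (1328 cells) and 16723.5 UMIs in run 2 (2040 cells). After filtering and removal of doublets and shallow clusters, 1298 control cells with 26884168 UMIs and 2797 knockout cells with 52361909 UMIs remained, with median depths of 18038.5 and 16721 UMIs per cell. Every comparison below is between these 2 libraries, with no replicate of either stated in the labels, and brackets after a value give its 95% counting interval.

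Nf2 itself (ENSMUSG00000009073.16, chromosome 11, 4765845 to 4849536, minus strand of GRCm38) had nearly the same level in both libraries. Its level in the retained cells was 21.6 CPM (19.9 to 23.4) in the control library, from 580 UMIs, and 20.1 CPM (18.9 to 21.4) in the library labelled knockout, from 1053 UMIs, a ratio of 0.932 (0.841 to 1.03). The runs gave 20.3 and 22.7 CPM in the control and 20.01 and 20.2 CPM in the library labelled knockout. The labels do not say which exons were removed, and 3′ tags can lie outside them, so this level does not check the labels. In what follows, the knockout library is the library labelled as such. Xist stood at 621 and 553 CPM in control and knockout, and no UMI of the Y-linked gene Uty was found in either, which allows up to 0.137 and 0.0704 CPM.

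The comparison of the libraries asks how the transcriptome of tumour endothelial cells differs where Nf2 is lost. Ankrd1, a transcript induced by YAP and TAZ (ENSMUSG00000024803.9, chromosome 19, 36111961 to 36120099), had the highest ratio of the genes named by rule, at 6.04 (5.46 to 6.69), with 15.3 CPM in the control and 92.5 CPM in the knockout library. Edn1, which encodes the vasoconstrictor endothelin 1 (ENSMUSG00000021367.8, chromosome 13, 42301476 to 42307990), was 4.58-fold higher (4.43 to 4.75) and reached 612 CPM in the knockout library. Cldn5, the main claudin of endothelial tight junctions (ENSMUSG00000041378.2, chromosome 16, 18776847 to 18778262), stood at 1038 CPM in the control and 274 CPM in the knockout library and was 3.79-fold lower (3.72 to 3.87). Efnb2, the ephrin that marks arterial endothelium (ENSMUSG00000001300.16, chromosome 8, 8617434 to 8661242), was 5.71-fold lower (5.30 to 6.15). The lowest of the named genes was Kcnj8, a subunit of an ATP-sensitive potassium channel (ENSMUSG00000030247.9, chromosome 6, 142564837 to 142571614), which was 7.51-fold lower (6.92 to 8.16), from 105 to 14.0 CPM.

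The other genes among the 12 highest ratios were the proteoglycan gene Bgn at 4.48 (4.10 to 4.90), the thrombin receptor gene F2r at 3.66 (3.38 to 3.96), the chemokine gene Cxcl12 at 3.49 (3.37 to 3.61), Mfap3l at 3.21, the macrophage growth factor gene Csf1 at 2.93, Fam198b at 2.90, Tgfb2 at 2.84, the P-selectin gene Selp at 2.79, Clu at 2.73 and the matrix protein gene Thbs1 at 2.73 (2.67 to 2.79). On the other side, the paternally expressed gene Peg3 was 6.41-fold lower, the neuropeptide gene Gal 4.99-fold, the mechanically gated channel gene Piezo2 4.89-fold, the netrin receptor gene Unc5b 4.83-fold, the phosphatase gene Dusp2 4.08-fold, the potassium channel subunit gene Kcne3 4.02-fold, the invariant chain gene Cd74 3.84-fold, the ecto-nucleotidase gene Nt5e 3.73-fold and the tenascin gene Tnc 3.21-fold. In each of these 24 genes both runs of the knockout library lay on the same side of both runs of the control library, which their choice by the ratio of the same runs largely fixes. F2r and Thbs1 were also among the 10 leading genes of cluster 8 (27 control and 274 knockout cells, median 6510 UMIs). That cluster was led by Gm26917, Gm42418, Lars2 and Malat1, and leaving it out was not tried. F2r, Tgfb2 and Mfap3l were among the 10 leading genes of cluster 0 (21 control and 778 knockout cells). Gal, Kcnj8, Piezo2, Kcne3 and Cldn5 were among those of cluster 3 (536 control and 8 knockout cells), and leaving out cluster 3 was not tried either. Genes that differ between the libraries had been kept in this clustering. Cd74 was 10.6-fold lower without run 2 of the knockout library, and Gal 3.02-fold lower without run 2 of the control library. Leaving out clusters 0, 6 and 11, which had a marker of another cell type and no endothelial marker among their leading genes and held 118 control and 1246 knockout cells, gave ratios of 1.81 for Tgfb2 and 4.40 for Selp, and made Peg3 4.07-fold and Gal 8.77-fold lower. The ratios of F2r and Mfap3l moved by no more than 1.5 times in that setting.

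**Figure D1:**
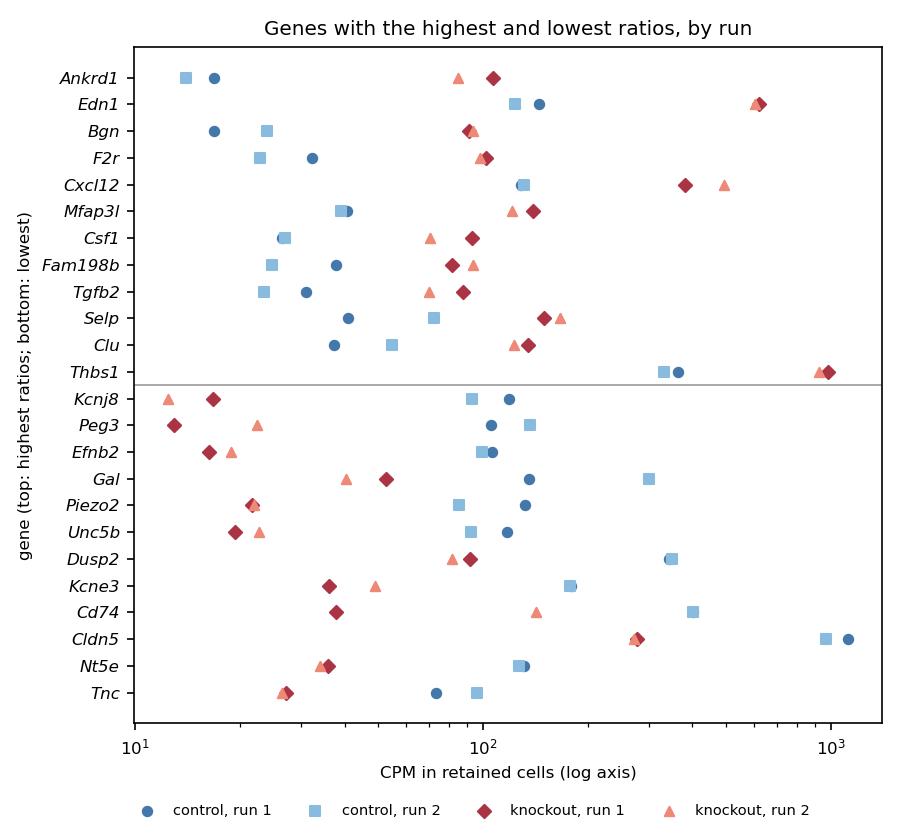
CPM in the retained cells (horizontal log axis) for the 12 genes with the highest and the 12 with the lowest ratios of knockout over control (vertical axis), with 1 mark for each run of each library. The knockout marks lie right of the control marks for the upper 12 genes, such as Ankrd1 (15.3 CPM in control, 92.5 in knockout), and left of them for the lower 12, such as Cldn5 (1038 and 274 CPM). The genes were chosen by the ratio of these same runs.

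Transcripts that YAP and TAZ are known to induce had mostly higher levels in the knockout library. Of 13 members with enough counts, 7 were higher, 2 were lower and 4 did not pass the size rule, and the median over 16 expressed members was 0.67 on the log2 scale (range of random lists −0.16 to 0.11). Cyr61 and Ctgf, matricellular proteins, were higher by ratios of 1.87 (1.83 to 1.91) and 1.65 (1.62 to 1.69), and the angiomotin gene Amotl2 by 2.01 (1.88 to 2.15). Crim1, Gadd45a and Tgfb2 were the further higher members. Igfbp3, a carrier of insulin-like growth factors, went the other way, from 6131 to 2011 CPM (3.05-fold lower, 3.03 to 3.07), as did Nt5e. Because Igfbp3 is so abundant, the summed level of the list was lower in the knockout library (7929.9 CPM in control, 4818 in knockout) although its median was higher. The kinases and adaptors of the Hippo pathway themselves differed little: 1 of 14 members was higher (Amotl2), 13 did not pass the size rule, and the list's median was −0.05, inside the random range. In sub-cluster 1 of the retained cells that list was lower than random lists, at −0.23. Wwtr1, which encodes TAZ, had a ratio of 0.709 (0.689 to 0.729), and Yap1 one of 0.963 (0.879 to 1.06).

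Genes of cholesterol synthesis and uptake were the list with the highest median, 1.05 on the log2 scale (random lists −0.17 to 0.12), and all 14 expressed members had ratios above 1. Of the 8 members with enough counts, 5 were higher and 3 did not pass the size rule. Insig1, which retains the sterol sensor in the endoplasmic reticulum (ENSMUSG00000045294.11, chromosome 5, 28071363 to 28078662), had a ratio of 2.59 (2.37 to 2.83), the isomerase gene Idi1 one of 2.37 (2.16 to 2.61), and Fdps and Msmo1 ratios of 2.04 and 1.67. Summed over the list, the level was 261 CPM in the control and 485 CPM in the knockout library, and the 4 pairs of runs of different libraries gave medians from 0.93 to 1.14.

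Notch pathway genes were lower in the knockout library: 7 of 9 members with enough counts were lower, none was higher and 2 did not pass the size rule, with a median of −0.63. Hey1, a direct Notch target (ENSMUSG00000040289.8, chromosome 3, 8663359 to 8667256), was 7.19-fold lower (6.36 to 8.15), the ligand gene Dll4 1.69-fold (1.63 to 1.75) and the receptor gene Notch1 1.66-fold (1.59 to 1.73). Among markers of arterial endothelium, 4 of 9 members were lower (Hey1, Efnb2, Unc5b and Vegfc), 3 were higher (Cxcl12, Clu and Edn1) and 2 did not pass the size rule. Their median was −0.90, while their summed level was higher, at 820 CPM in the control and 1425 CPM in the knockout library, because Edn1 and Cxcl12 are the most abundant members in the latter, and the median was −0.36 over members with at least 20 CPM. Vegfc was 2.44-fold lower (2.21 to 2.70), and 1.57-fold lower without clusters 0, 6 and 11. Venous markers went both ways, with 4 of 14 higher, 3 lower and 7 not passing the size rule (median 0.13). With the same sub-cluster weights in both libraries these markers had a median of −0.060. Their summed level was lower, at 7198 CPM in the control and 5127 CPM in the knockout library, mostly through Ctla2a. Ackr1, a chemokine-binding receptor of venules, was 4.46-fold higher (3.97 to 5.02), Selp and Lrg1 were higher too, while Vwf was lower with a ratio of 0.643 (0.622 to 0.666). The ratio of Ackr1 was 7.08 without clusters 0, 6 and 11 and 2.72 with the same sub-cluster weights in both libraries.

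Genes of tip cells, the leading cells of vessel sprouts, did not move together. Of 27 members 11 were lower, 3 were higher and 13 did not pass the size rule, with a median of −0.48. Unc5b, the sulphotransferase gene Chst1 (2.74-fold, 2.62 to 2.87) and the activin subunit gene Inhbb (2.33-fold, 2.26 to 2.39) were lower, whereas the sprouting genes Apln, Esm1 and Angpt2 were higher, with ratios of 1.86, 1.61 and 1.51. Among the receptors and ligands of the VEGF and angiopoietin families, Vegfc, Flt4, Flt1 and Nrp1 were lower, Angpt2 was higher, and 8 of 13 did not pass the size rule (median −0.19). Flt1, the abundant VEGF receptor 1, was 1.80-fold lower (1.77 to 1.83) and Flt4 2.01-fold lower (1.88 to 2.15). Capillary markers had a median of −0.44, with 4 of 13 lower, 2 higher and 7 not passing the size rule. Btnl9 was 4.51-fold lower (4.06 to 5.01) and Gpihbp1, which anchors lipoprotein lipase, 2.41-fold lower (2.38 to 2.45), while Car4 was 2.70-fold higher (2.53 to 2.88). The ratio of Car4 was 4.87 without run 2 of the control and 1.67 without run 2 of the knockout library, and the runs of the knockout library differed in the capillary median by 0.46, the median being −0.68 without run 2. Thinned to 2000 UMIs per cell, Btnl9 was 2.65-fold lower.

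Junction and basement membrane genes were lower as groups. In the junction list 3 of 13 members were lower (Cldn5, Jup and Cdh5), none was higher and 10 did not pass the size rule, and 13 of 14 expressed members had ratios below 1 (median −0.37). Cdh5, the endothelial cadherin, was 1.56-fold lower (1.54 to 1.58) and Jup, which encodes plakoglobin, 1.69-fold lower (1.58 to 1.80), while Pecam1, the antigen of the sort, had a ratio of 0.929 (0.916 to 0.942). Of the basement membrane and integrin genes, 10 of 19 were lower, 2 were higher and 7 did not pass the size rule (median −0.59). Itga6 was 2.33-fold lower (2.27 to 2.40), Lamb1 2.24-fold lower (2.17 to 2.31), and the collagen IV genes Col4a1 and Col4a2 had ratios of 0.642 and 0.665. The fibronectin gene Fn1 went the other way, with 775 CPM in the control and 1657 CPM in the knockout library (ratio 2.14, 2.11 to 2.17), as did Lamb2. In sub-clusters 1 and 7 of the retained cells, however, Fn1 was lower, with ratios of 0.767 (0.707 to 0.832) and 0.775 (0.731 to 0.821). General endothelial markers had a median of −0.25, with 4 of 19 lower (Cldn5, Cdh5, Vwf and the transcription factor gene Sox18), none higher and 15 not passing the size rule. Sox18 was 1.75-fold lower (1.71 to 1.80).

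Genes for leukocyte adhesion and inflammatory signalling were higher between the libraries, though by sizes that depended on the run and the sub-cluster. Within sub-clusters 1, 3 and 6 the adhesion list was inside the random range (0.083, −0.00086 and 0.062). The list of NF-κB targets was inside it in sub-clusters 0 and 6 (0.12 and 0.099). Of the adhesion genes, 6 of 11 were higher (Ackr1, Cxcl12, Selp, Icam1, Cxcl1 and Ccl2), none was lower and 5 did not pass the size rule, with a median of 0.72. Pairs of runs gave medians from 0.22 to 1.19, against 0.24 between the control runs, and the median was 0.28 without run 1 and 1.008 without run 2 of the control. Of the NF-κB target genes, 4 of 13 were higher and 9 did not pass the size rule (median 0.42, and 0.18 without run 2 of the knockout library): the chemokine genes Cxcl1, Ccl2 and Cxcl2 had ratios of 2.30 (2.17 to 2.43), 2.07 (2.01 to 2.12) and 2.06 (1.93 to 2.20). With cells gated one by one, the ratio of Cxcl2 was 1.30. MHC class II genes were lower, in 4 of 4 members with enough counts (median −1.58), but the runs of the knockout library differed by 1.44, and the median was −2.60 without run 2 and −1.23 without run 1. H2-Eb1 was 3.96-fold lower (3.62 to 4.33) and H2-Aa 3.11-fold lower (2.86 to 3.38), and without run 2 of the knockout library they were 9.60-fold and 7.97-fold lower. H2-Aa was 4.71-fold lower in thinned cells. MHC class I genes had a median of 0.13 and none of 18 passed the size rule; H2-T23 had a ratio of 1.35 (1.29 to 1.41) with overlapping runs, and without run 2 of the knockout library the list was at −0.040 and H2-T23 at a log2 ratio of −0.033. The interferon response was inside the random range at 0.03, with none of 29 members past the size rule. In sub-clusters 0, 3 and 7, however, the list was higher than random lists (0.22, 0.41 and 0.37). It was inside the random range in 1, 2 and 6 (0.033, −0.074 and −0.15). Cxcl10 had a ratio of 1.38 (1.35 to 1.42), its runs overlapped, and the ratio was 2.15 without clusters 0, 6 and 11. Without run 2 of the knockout library the interferon list had a median of −0.28 and Cxcl10 a log2 ratio of −0.10. Macrophage and neutrophil markers together summed to 189 CPM (184 to 194) in the control and 225 CPM (221 to 229) in the knockout retained cells. Their runs overlapped (178 and 198 CPM in the control, 173 and 254 CPM in the knockout library), and the control was higher with cells gated one by one (262 against 211 CPM) and with shallow clusters kept (276 against 233 CPM).

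Markers of endothelial-to-mesenchymal transition had a median of 0.26, with 3 of 8 higher and 5 not passing the size rule. Tgfb2 and Fn1 were among the higher members over all retained cells, though not in sub-cluster 1, where Tgfb2 had a ratio of 0.815 (0.636 to 1.05) and Fn1 was lower, and the median was −0.11 over members with at least 20 CPM and −0.0067 without run 1 of the knockout library. The summed level of the list was lower in the knockout library, at 11699 CPM in the control and 11262 CPM. The list of p53 targets and apoptosis genes had a median of 0.39, with 2 of 10 higher, 1 lower and 7 not passing the size rule: the survival gene Bcl2l1 and Ccng1 were higher with ratios of 1.81 (1.65 to 1.98) and 1.61 (1.47 to 1.77), and Bcl2, another survival gene, was 2.19-fold lower (1.98 to 2.43). Flow-responsive genes had a median of 0.15, with Edn1 and Txnip (ratio 1.91, 1.84 to 1.995) higher, Timp3 1.74-fold lower (1.68 to 1.79) and 7 of 10 not passing the size rule. Timp3 was 2.61-fold lower without run 2 of the knockout library. In sub-cluster 1 the flow-responsive list was lower than random lists, at −0.31. The G2/M list had a median of −0.14 and none of its 19 members passed the size rule, Cenpf having a ratio of 0.737 (0.695 to 0.782) with overlapping runs. Without clusters 0, 6 and 11 the list was at 0.48, Cenpf at a ratio of 1.28 and S-phase genes at 0.58, and without run 2 of the control the list was at 0.097.

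Further lists lay inside the random range over all retained cells, though not all of them in every sub-cluster. S-phase genes were higher than random lists in sub-clusters 1, 2 and 6 (0.17, 0.35 and 0.69) and lower in 0 (−0.37). Hypoxia and glycolysis genes were higher in 2 (0.26) and lower in 6 and 7 (−0.15 and −0.18). Immediate early genes were lower in 1 and 6 (−0.43 and −0.16), as were unfolded protein response genes in 3 (−0.31). The medians that follow are over all retained cells. Actin and SRF target genes had a median of −0.06, with Tpm1 higher (ratio 2.10, 2.05 to 2.14) and Msn and Cnn3 at 0.733 and 0.766. S-phase genes had a median of 0.08, hypoxia and glycolysis genes one of 0.03, with Ero1l, Pfkp and Slc2a1 at 0.689, 0.722 and 0.739, and unfolded protein response genes one of −0.05. Oxidative phosphorylation genes had a median of 0.08, with Ndufa4 higher (1.69, 1.63 to 1.76) and Cox6c at 1.29. Genes of fatty acid handling had a median of −0.0046, with Gpihbp1 lower, Meox2 at a ratio of 1.498 (1.44 to 1.55) and Cd36 higher at 1.54 (1.49 to 1.59). The ratio of Cd36 was 0.931 without run 2 of the knockout library and 1.009 with the same sub-cluster weights in both libraries. Immediate early genes had a median of −0.07, with Hspb1 higher (2.24, 2.19 to 2.30) and Zfp36 and Egr1 1.88-fold and 1.74-fold lower, and mitochondrial transcripts one of 0.06, with mt-Nd4l at 1.40. Only 3 lymphatic markers were expressed, too few for a percentile (median −1.01). Among them Nts was 2.58-fold lower (2.43 to 2.74) with overlapping runs, and from 1.34-fold lower without run 1 of the control to 12.4-fold lower without run 2 of the knockout library.

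By the size rule, 162 of 5842 genes were higher and 319 were lower in the knockout library. Between the 2 runs of the control library the same rule gave 20 higher and 28 lower genes, and between those of the knockout library 55 and 15. Of all genes tested, 3785 (64.8%, against 33.3% by chance order of the runs) had both runs of the knockout library on 1 side of both runs of the control library. Among the counted genes this held for 161 of the higher and 317 of the lower genes, which their choice by the ratio of the same runs largely fixes. Of 29 lists with a percentile, 9 were higher and 10 lower than random lists, but 16 lists were also outside the random range between the control runs and 15 between the knockout runs, so the percentile alone does not set the libraries apart. Beyond the runs of either library were 10 lists. Higher were YAP and TAZ targets, cholesterol genes, and the list of p53 targets and apoptosis genes. Lower were tip cell, VEGF and angiopoietin, Notch, arterial, general endothelial, junction and basement membrane genes. The lower lists share members and are not separate results. Cdh5 and Cldn5 are in the general endothelial and junction lists, and Hey1 is in the Notch and arterial lists. The tip cell list shares Dll4 with Notch, Unc5b with arterial, Flt4 and Nrp1 with VEGF and angiopoietin, and Nid2 and Lamb1 with basement membrane genes. Differences between mice or between library preparations cannot be separated from the loss of Nf2 with 1 library per group.

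**Figure D2:**
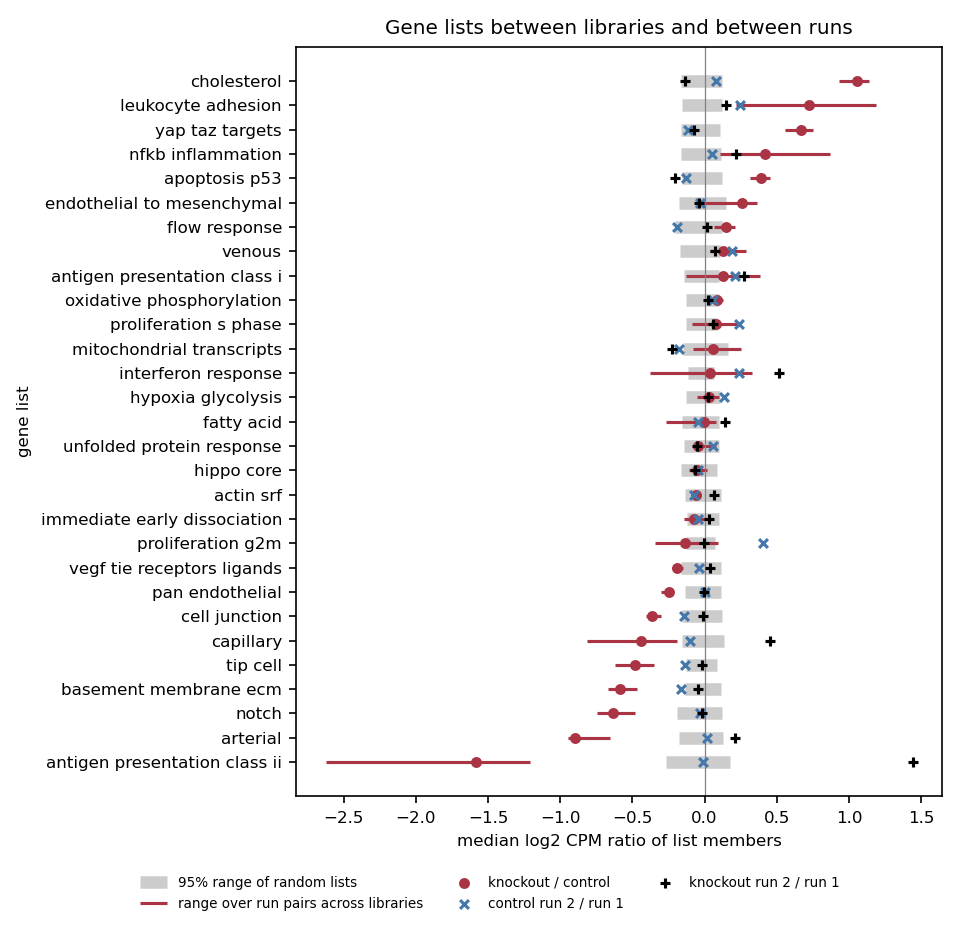
Median log2 CPM ratio (horizontal axis) of each gene list (vertical axis): red points give knockout over control, red lines the range over the 4 pairs of runs, crosses and plus signs the runs of 1 library, and grey bars the 95% range of random lists. Cholesterol (1.05), YAP and TAZ targets (0.67), Notch (−0.63) and arterial genes (−0.90) lie apart from the marks of the runs, while class II genes (−1.58) differ between the knockout runs by 1.44.

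Several of the list differences were also present within groups of similar cells, and others in part of them. Retained cells clustered without the genes that differ between the libraries fell into 12 sub-clusters, of which sub-clusters 0, 1, 2, 3, 6 and 7 held at least 50 cells of each library. Cholesterol genes had medians from 0.995 to 1.36 in these 6, Notch genes from −0.77 to −0.50, basement membrane genes from −0.69 to −0.44, junction genes from −0.43 to −0.26 and arterial genes from −1.96 to −0.29. YAP and TAZ targets were more uneven, with a median of 0.82 in sub-cluster 0 and 0.05 in sub-cluster 1, whose leading genes included Ednrb and Ramp3. The ratio of Edn1 ran from 2.43 (2.28 to 2.58) in sub-cluster 3 to 7.55 (6.94 to 8.22) in sub-cluster 0, and that of Cldn5 from 0.213 to 0.454. The p53 list was inside the random range in sub-clusters 6 and 7 (0.019 and −0.096), the VEGF and angiopoietin list in sub-cluster 7 (−0.13), the capillary list in sub-cluster 7 (0.016) and YAP and TAZ targets in sub-cluster 1. The adhesion list was inside it in sub-clusters 1, 3 and 6, NF-κB targets in 0 and 6, and class I genes in 1, 2 and 6. Some lists called higher were lower than random lists in places. These were flow-responsive genes in sub-cluster 1 (−0.31), venous markers in 0 and 3 (−0.29 and −0.35) and endothelial-to-mesenchymal markers in 7 (−0.34). The G2/M list, called lower, was higher in sub-cluster 1 (0.39). Differences between sub-clusters were not tested.

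**Figure D3:**
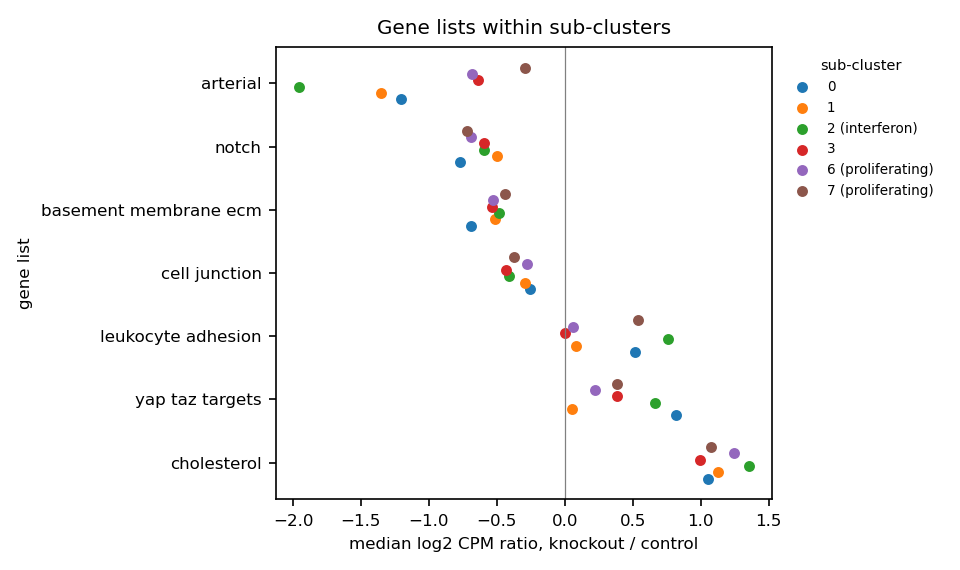
Median log2 CPM ratio of knockout over control (horizontal axis) for 7 gene lists (vertical axis), with 1 point for each sub-cluster holding at least 50 cells of each library. The cholesterol points lie between 0.995 and 1.36 and the Notch points between −0.77 and −0.50, while those of YAP and TAZ targets spread from 0.05 to 0.82.

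Sub-cluster 2, led by the interferon-induced genes Cxcl10, Ifit2 and Rsad2, held 17.8% (15.8 to 19.99) of the control and 13.1% (11.9 to 14.4) of the knockout retained cells. The knockout runs differed more than that, at 8.16% (6.66 to 9.87) and 16.7% (14.9 to 18.6), so the share does not set the libraries apart. Sub-cluster 4, led by Tagln, Sult1a1 and Apoe, had 3 capillary markers among its 25 leading genes, the number needed for that name. It held 23 control (1.77%) and 333 knockout cells (11.9%), with 6.88% and 15.6% in the knockout runs. Sub-cluster 5 held 33 and 269 cells at a median of 6605 UMIs. It was led by Gm26917, Gm42418 and Lars2, with F2r, Fn1 and Thbs1 among its 10 leading genes. Sub-cluster 8, led by Hbb-bs, Piezo2 and Btnl9, held 136 and 12 cells. Their leading genes include ones that differ between the libraries, and each may be 1 library and not a kind of cell.

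Cells with transcripts of the G2/M list made up nearly equal shares. At 2000 UMIs per cell, 20.1% (17.9 to 22.4) of 1276 control cells and 19.5% (18.03 to 21.01) of 2781 knockout cells carried at least 2 UMIs of G2/M genes such as Mki67 and Top2a, after 22 and 16 shallower cells had been left out. The runs gave 20.1% and 20.1% in the control and 20.5% and 18.8% in the knockout library. Without thinning the shares were 67.2% and 69.5%. Free RNA can add such UMIs to cells that do not divide, and no cell type lacking these genes was there to measure it. A difference between the libraries was not detectable among all retained cells. Without clusters 0, 6 and 11 the share was 15.1% (13.1 to 17.3) in the control and 20.7% (18.7 to 22.8) in the knockout library, and the G2/M list had a median of 0.48. Removing these clusters shifts the share by construction, since cluster 11 was led by mitotic genes such as Cdc20 and Cenpa and cluster 0, without such leading genes, held 21 control and 778 knockout cells.

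The share of retained cells was 53.1% (51.1 to 55.1) in the control and 88.9% (87.8 to 89.98) in the knockout library, and it followed the runs: 41.1% and 82.7% in the control, 93.3% and 85.9% in the knockout library. The share depends on depth, because all clusters left out had few UMIs per cell. Clusters 2, 4, 10 and 13 among them were also led by leukocyte markers, and cluster 2 alone held 596 of the 1145 control cells left out. Gated one by one on endothelial markers, 94.9% and 95.2% of the cells passed. That gate asked for at least 3 detected endothelial markers and no UMI of Ptprc, Col1a1 or Epcam. Cells of the shallow clusters passed it too, so it does not tell why they are shallow.

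**Figure D4:**
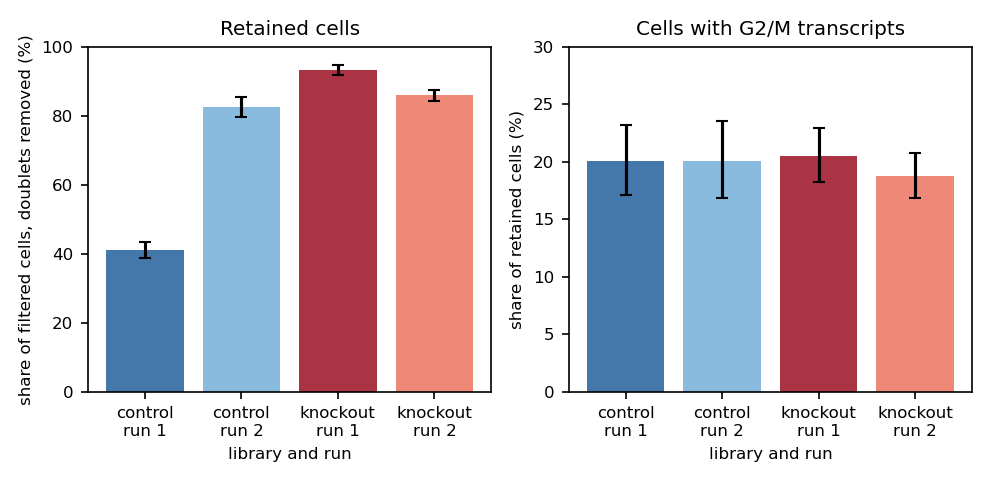
Share of filtered cells retained (left, vertical axis in percent) and share of retained cells with G2/M transcripts at 2000 UMIs per cell (right, percent) for each run of each library, with exact 95% intervals as error bars. The retained share is lowest in run 1 of the control (41.1%), and the G2/M shares lie between 18.8% and 20.5%.

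Markers of other cell types were low among the retained cells. Endothelial markers summed to 12363 CPM in the control and 9791 CPM in the knockout library. Monocyte and macrophage markers summed to 111 CPM (107 to 115) and 130.2 CPM (127 to 133), neutrophil markers to 78.4 and 95.1 CPM, fibroblast markers to 21.5 and 19.2 CPM, T-cell markers to 6.06 and 7.39 CPM, NK-cell markers to 2.31 and 1.64 CPM and B-cell markers to 83.6 and 106 CPM, of which Ebf1 made up 82.2 and 105 CPM. Dendritic-cell markers summed to 484 and 353 CPM, most of it from Fscn1, which is also a tip-cell gene (458 and 328 CPM), mast-cell markers to 268 and 269 CPM, and platelet markers to 166 and 97.4 CPM. Single genes carried these sums too, with Kit at 239 and 239 CPM in the mast-cell class, whose marker Cpa3 had no UMI in either library, and Itgb3 at 149 and 83.1 CPM in the platelet class. Lymphatic endothelial markers summed to 103 and 73.5 CPM, mostly from Flt4 and Lyve1. Erythroid markers summed to 50.5 CPM in the control and 22.9 CPM in the knockout library, with overlapping runs (83.8 and 21.3 CPM in the control, 4.32 and 33.2 CPM in the knockout library). Pericyte and smooth muscle markers summed to 176 CPM (171 to 181) in the control and 72.5 CPM (70.2 to 74.8) in the knockout library, the members with the most counts being Kcnj8, Abcc9 (50.03 and 12.3 CPM) and Tagln (4.09 and 25.3 CPM). Epithelial markers were higher in the knockout library, at 7.89 CPM (6.86 to 9.02) and 38.2 CPM (36.6 to 39.9), most of it from Cldn4 (5.24 and 30.3 CPM). Melanocyte markers stood at 2.64 and 2.502 CPM, Schwann-cell markers at 2.75 and 4.41 CPM, and adipocyte markers at 0 CPM, with an upper limit of 0.137, and 0.592 CPM.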

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

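The test of the shallow clusters for RNA of leukocytes was chosen only after the result was seen, as was the comparison of genes between sub-clusters, while the test of nuclear RNA was written down before its result.

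Cxcl2, a neutrophil-attracting chemokine gene, stood out among the named genes because its ratio of knockout over control went in opposite directions in sub-clusters of the retained cells, with an interval wholly below 0.8 in 1 of them. The ratio was 2.72 (2.29 to 3.25) in sub-cluster 2, led by interferon-induced genes, and 0.571 (0.436 to 0.751) in sub-cluster 6, led by the mitotic genes Cenpa, Ccnb2 and Cdkn3. Other named genes did so with intervals that reach above 0.8 or lie near 1: Fn1 had ratios of 3.58 (3.41 to 3.76) in sub-cluster 2 and 0.767 (0.707 to 0.832) in sub-cluster 1, Cd36 of 1.90 (1.70 to 2.13) in sub-cluster 7 and 0.751 (0.699 to 0.808) in sub-cluster 2, and Flt1 of 1.08 (1.03 to 1.14) in sub-cluster 7 and below 1 elsewhere. The intervals cover counting error only, and the differences were not tested.

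Epithelial markers stood out in the shallow clusters, which enter no comparison of genes, at 38.4 CPM (28.0 to 51.4) in the knockout library against 13.1 CPM (9.24 to 17.9) in the control library. Run 1 of the knockout library carried the value, at 87.2 CPM (58.0 to 126) from 28 UMIs, against 19.97 CPM (11.6 to 32.0) in run 2, and the control runs were at 11.1 and 23.3 CPM. In the retained cells of the knockout library the level was 38.2 CPM. Without Cldn4 the class summed to 2.64 CPM in the control and 7.96 CPM in the knockout retained cells, most of the latter from Wfdc2 (0.037 and 4.68 CPM, ratio 126, 22.4 to 4988), and Epcam, Krt8 and Krt18, abundant in epithelial cells, stood at 0.0955, 0.936 and 1.59 CPM in the knockout library.

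The shallow clusters held 58.9% of the cells of run 1 of the control library and between 6.66% and 17.3% of those of the other runs. In cluster 4, present in all 4 runs, RNAs that stay in the nucleus, such as Malat1 (468 CPM against 14846 CPM in run 1 of the control), had median log2 ratios to the retained cells of −3.69 or lower, with median mitochondrial shares of 0.151% to 0.488% against 3.12% to 3.71%, values consistent with fragments of cells that carry little nuclear RNA and few mitochondria. In the other shallow clusters of run 1 of the control (919 cells) the nuclear RNAs had a median of −0.40 and the mitochondrial share was 3.75%, so that the test leaves open whether these are fragments or small whole cells. Macrophage and neutrophil markers were at least 2.37-fold higher (1.98 to 2.83, in run 1 of the knockout library) in the shallow than in the retained cells of every run, and 6.56-fold in run 1 of the control (S100a9 390.2 against 36.3 CPM, Lyz2 114 against 14.7 CPM), so free RNA or fragments of leukocytes may add to them, although the cells were sorted on CD31, which some leukocytes and platelets also carry. No biological explanation of the shallow cells was tested.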

How the results depend on the processing

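Leaving out runs, keeping shallow clusters, requiring 5000 UMIs per cell, other sub-cluster resolutions and leaving out clusters 0, 6 and 11 were chosen after the data were seen. No paired analysis was possible because each group has 1 library. The counts of lists, 9 higher and 10 lower, stayed within 1.5 times under all 21 settings, and those of genes, 162 and 319, in 20 settings. They were 77 and 182 at a mean of 50 CPM, 354 and 524 at 5 CPM, and 61 and 95 at a ratio of 2, by construction of these thresholds. The medians kept their sign under every setting run for cholesterol (0.88 to 1.12), YAP and TAZ targets (0.54 to 0.75), Notch (−0.71 to −0.52), arterial (−1.21 to −0.36), basement membrane (−0.65 to −0.49) and junction genes (−0.43 to −0.32). Over all alternatives, 1058 values of named genes and 553 of lists stayed within their spread, 496 and 48 moved beyond it, and 6 values of genes whose interval excluded a ratio of 1 and 7 of lists outside the random range turned round. Changes of sign of lists inside the random range are not in that count, among them the interferon list at −0.28 without run 2 of the knockout and S-phase genes at −0.027 without run 1 of the control. Nf2 had a ratio of 0.817 (0.588 to 1.14) in cells thinned to 2000 UMIs.

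The cause of the following changes was not tested unless stated. Directions turned round for Cxcl10 as a mean over cells (−0.066, log2) and for the G2/M list without dividing cells (0.18, as built). They also did for venous markers with the same sub-cluster weights in both libraries (−0.060). Endothelial-to-mesenchymal markers turned round over members of at least 20 CPM (−0.11, fewer members). Without run 2 of the control, Cenpf was at 0.046 and the G2/M list at 0.10; without run 1 of the knockout, endothelial-to-mesenchymal markers were at −0.0067; without run 2 of the knockout, H2-T23 was at −0.033, Cxcl10 at −0.10, Cd36 at −0.10 and class I genes at −0.040. Without clusters 0, 6 and 11, Cenpf was at 0.35 and the G2/M list at 0.48.

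The retained share of control cells was 50.1% with no filter, and 77.4% (92.4% of knockout cells) with the stricter filter; it was 90.1% of knockout cells at resolution 1.2, 94.9% and 95.2% with cells gated one by one, and 48.3% and 49.3% without clusters 0, 6 and 11. Without run 1 or run 2 it was 82.7% or 41.1% in the control and 85.9% or 93.3% in the knockout library. The share of the interferon sub-cluster in the control was 14.4% with the stricter filter and 20.5% with doublets kept. In control and knockout it was 10.0% and 9.08% at resolution 0.4, 10.8% and 11.7% with cells gated, 23.003% and 17.1% without dividing cells, 5.98% and 8.11% with shallow clusters kept, 10.3% and 8.96% without clusters 0, 6 and 11 and 10.6% and 8.40% at sub-cluster resolution 0.4, so its order depends on the choice of cells. At resolution 1.2 it was 11.503% in the knockout. Without run 1 or run 2 it was 26.1% or 14.0% in the control and 11.05% or 8.24% in the knockout library. Cells with G2/M UMIs were 36.8% and 39.8% at 1 UMI or more, 15.4% and 13.6% at 3 or more, 67.2% and 69.5% without thinning, 14.3% and 12.9% at 1000 UMIs, and 15.1% and 20.7% without clusters 0, 6 and 11. Depth limits statements on genes below 20 CPM.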

Other observations

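The gene groups and tests in this part were chosen only after the values were seen, except the test of the imprinted genes. The limits of that test were written down before its result, apart from a margin given below.

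Receptors cleaved by thrombin and related proteases differed in both directions. F2rl1, which encodes protease-activated receptor 2, was at 2.60 CPM in the control and 53.9 CPM in the knockout library, a ratio of 20.7 (16.3 to 26.6), with 53.4 and 54.1 CPM in the runs of the knockout library. F2rl1 and F2r were among the 10 leading genes of cluster 0, which held 21 control and 778 knockout cells. The ratio of F2rl1 was not computed without that cluster or within sub-clusters, so it may not hold across the retained cells. F2r had a ratio of 3.66 (3.38 to 3.96) and F2rl2 one of 3.21 (2.86 to 3.60), while F2rl3, the receptor 4 gene, was 1.97-fold lower, at 25.3 CPM in the control and 12.9 CPM in the knockout library.

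Kcnj8 is best known from pericytes and is a marker of that class here. With Kcnj8 left out, the pericyte markers summed to 70.9 CPM in the control and 58.5 CPM in the knockout library (ratio 0.825, 0.779 to 0.874), a sum of lower Abcc9 (50.03 and 12.3 CPM) and higher Tagln (4.09 and 25.3 CPM, ratio 6.18, 5.08 to 7.57). With Tagln left out instead, they summed to 172 and 47.2 CPM (ratio 0.275, 0.261 to 0.288), and Rgs5, an abundant pericyte transcript, was at 4.65 and 4.79 CPM. Within sub-clusters the ratio of Kcnj8 ran from 0.0942 (0.0797 to 0.111) to 0.343 (0.281 to 0.418).

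The higher level of cholesterol genes in the knockout library was weighed against technical explanations. A different mix of sub-clusters is argued against by the medians within those holding at least 50 cells of each library, the lowest being 0.995. States marked by the 2073 genes left out of that clustering are not addressed, since such cells could share a sub-cluster. Sub-clusters 4, 5 and 8, whose cells lay mostly in 1 library, are not covered either. Variation like that between runs is argued against as well, since the medians between runs of the same library were at most 0.14 in size, against at least 0.93 between runs of different libraries. With cells thinned to 2000 UMIs the median was 0.89. A difference between mice or library preparations and the loss of Nf2 itself cannot be told apart, since there was 1 library per group, and both may contribute.

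Peg3, which is expressed from the paternal allele, was 6.41-fold lower in the knockout library, and so were Mest (2.48-fold) and Asb4 (2.31-fold), also imprinted. Over 8 further imprinted genes other than Peg3 and Mest, 6 had ratios below 1, with a median of −0.11 (log2) inside the range of matched random lists (−0.21 to 0.20). The median lay above the limit written down beforehand for imprinted genes not being lower as a group. The test as run also asked for a margin set by the width of the random range, which the written rule did not hold. With that margin, 8 genes leave open whether imprinted genes were lower as a group.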
